A study of Mus musculus with 6 samples.

How the data were processed

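Gene expression was measured in tumour-associated macrophages, which are macrophages taken out of a tumour, from mice bearing hepa1-6 tumours in the liver. Hepa1-6 is a mouse hepatoma cell line. Per the labels' protocols, the cells were sorted by flow cytometry, their total RNA was extracted, and biotin-labelled material was hybridised to Affymetrix Mouse Gene 1.0 ST arrays. The 6 arrays fall into 3 from mice given vehicle and 3 from mice given PLX3397, an inhibitor of the kinases CSF1R, KIT and FLT3. Groups and replicate numbers were taken from the sample titles. The description field of each sample also carries a second name, of macrophages treated with LPS and interferon-gamma for vehicle samples and with IL4 for treated samples. These names disagree with the titles, sources and treatment labels and were not used for grouping. The labels call the samples biological replicates without saying whether each came from a separate animal, so the p-values measure only the spread between these samples.

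The authors deposited log2 values per probe set, already on a similar range on the 6 arrays. Their summarisation, normalisation between arrays and any filter are not given in the sources used here. The submitters' processing notes name MAS5 with no version and no role. The base of the logarithm was taken from the values, which ran from 1.57 to 13.5. Array medians lay between 4.21 and 4.25 in the vehicle group and between 4.32 and 4.35 in the PLX3397 group, so the values were used as deposited, under a rule that called for quantile normalisation only where medians differed by over 0.5. Scanner files, and with them hybridisation dates, were not used here, so no batch could be tested.

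The table holds 28941 probe sets, of which 21789 carry exactly 1 gene symbol in the platform annotation, 1621 carry several and 5531 are unnamed here. Of the probe sets with 1 symbol, 21698 matched a current gene record by Entrez identifier, and 0 were renamed. Each gene was represented by its brightest probe set over the 6 arrays, a choice that mattered for the 999 genes with more than 1, which left 19938 genes. Probe sets with several symbols or none were tested apart from these genes. Gene families with near-identical members, such as Stfa, Ms4a, Ly6c, H2 and the ribosomal protein genes, can share probes, and values of single members are uncertain for that reason.

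Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Changes are PLX3397 minus vehicle on the log2 scale. A further 31 gene lists, 601 of whose 640 memberships were measured (4 of them through a synonym), were tested with camera at a preset correlation between genes of 0.01, with adjustment over the lists. Camera with an estimated correlation, camera on ranks and fry were run as comparisons. Some lists share members, such as Arg1, Fn1, Ccl17, Ccl22 and Mmp8, so their calls are not independent of each other. The lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted genes, then Csf1r, Kit, Flt3 and 8 macrophage markers always, and 2 to 4 members of each list with the largest change.

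The background level was set after the data were seen. It is the 95th percentile of 1194 olfactory and vomeronasal receptor genes on each array, and lay between 3.52 and 3.58. Where a gene exceeded it on none of the 3 arrays of a group, the fold is a bound ("at least"), the mean of the brighter group against the mean of the background level or the gene's own value, whichever was higher on each array. With 3 arrays per group the number of arrays limits the precision, and the smallest p an exact permutation test of 1 gene can give is 0.1.

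The gene and list tests were tested on simulated data with the spread of the 19938 genes of this comparison. Of 66 genes shifted by 0.5 log2, 63.6% were recovered, of 67 shifted by 1 log2, 92.5%, and of 67 shifted by 2 log2, 100%. In the data 7539 genes passed the threshold, and the adjusted threshold is stricter where few genes change. These rates therefore do not carry over to the data. In that run 177 genes were called, of which 6 were false, and the list test called 1 of 31 lists, the 1 that had been shifted. Each simulated gene was drawn independently of the others, so the run could not show false list calls that arise from correlation between genes. Alternatives covered quantile normalisation, centring of each array, 2 filters on dim genes, a filter on the background level added after the data were seen, the replicate number as a block, other variance settings, array weights, the mean of a gene's probe sets, all probe sets, other thresholds, and leaving out each array. Figures were drawn with matplotlib 3.10.9 and tables were joined with pandas 2.3.3 in Python 3.11.15.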

Results

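Tumour-associated macrophages sorted from hepa1-6 tumours implanted in the liver of C57BL/6 mice were profiled on 6 arrays, 3 from the vehicle group and 3 from the PLX3397 group. The comparison asked which transcripts differ between macrophages of tumours exposed to the CSF1R inhibitor and those of control tumours. Of 19938 genes, 12974 exceeded the background level on all 3 vehicle arrays and 13239 on all 3 PLX3397 arrays. Values below are means ± SD of log2 values with n = 3 per group, and changes carry the standard error (SE) of the limma fit.

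Macrophages from PLX3397-treated mice had far more transcript of the chemokines Ccl17 and Ccl22, the arginine-degrading enzyme Arg1 and the collagenase Mmp8. Ccl17 rose from 4.59 ± 0.27 to 11.78 ± 0.10, a change of 7.19 (SE 0.13, adjusted p = 4.51e-10), and Arg1 rose from 5.19 ± 0.19 to 10.76 ± 0.39, a change of 5.57 (SE 0.18, adjusted p = 1.10e-08). Stfa3, a cysteine protease inhibitor of a family with near-identical members, was not above background in vehicle and was at least 268-fold higher with PLX3397 (adjusted p = 1.15e-10). Apoe, a lipid carrier that was among the bright transcripts of the vehicle group at 12.92 ± 0.06, fell by 4.52 to 8.40 ± 0.28 (SE 0.13, adjusted p = 6.27e-09). The integrin subunit Itga4 fell by 3.62 and the membrane protein gene Ms4a4a by 4.31.

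The other large rises were those of the co-stimulatory receptor Tnfrsf9 (6.43), Plet1 (6.12), the fusion-related receptor Dcstamp (5.92), the carbonic anhydrase Car4 (5.87), AA467197 (5.66), the opioid peptide precursor Penk (5.56), Mmp8 (5.48) and Ccl22 (5.40). Trem1, an activating receptor of myeloid cells, was at least 44.2-fold higher. The other large falls were those of Cd300e (-3.41), Ms4a4c (-3.36), Ms4a6b (-3.25), Gpr31b (-3.22), Rasgrp1 (-3.20), Fnbp1l (-3.19) and Treml4 (-3.13), with Adgre4 at least 8.55-fold and Zfp558 at least 6.24-fold lower. In total 7539 genes passed the threshold, 3900 higher and 3639 lower with PLX3397, and 9021 had an unadjusted p below 0.05. Changes of at least 1 log2 numbered 640 upward and 805 downward, and changes of at least 3 log2 numbered 89 and 16. The groups did not overlap in 49.3% of genes, against 10% by chance. The split between rises and falls depended on scaling, with 51.7% of calls higher as deposited and 30.6% higher when each array was centred on its median. That centring moved the median change of all genes from 0.04 to -0.09. Genes with a mean level of 4 to 6 had a median change of 0.12 and those of 6 to 8 one of -0.12. With quantile normalisation these were 0.02 and -0.02.

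**Figure D1:**
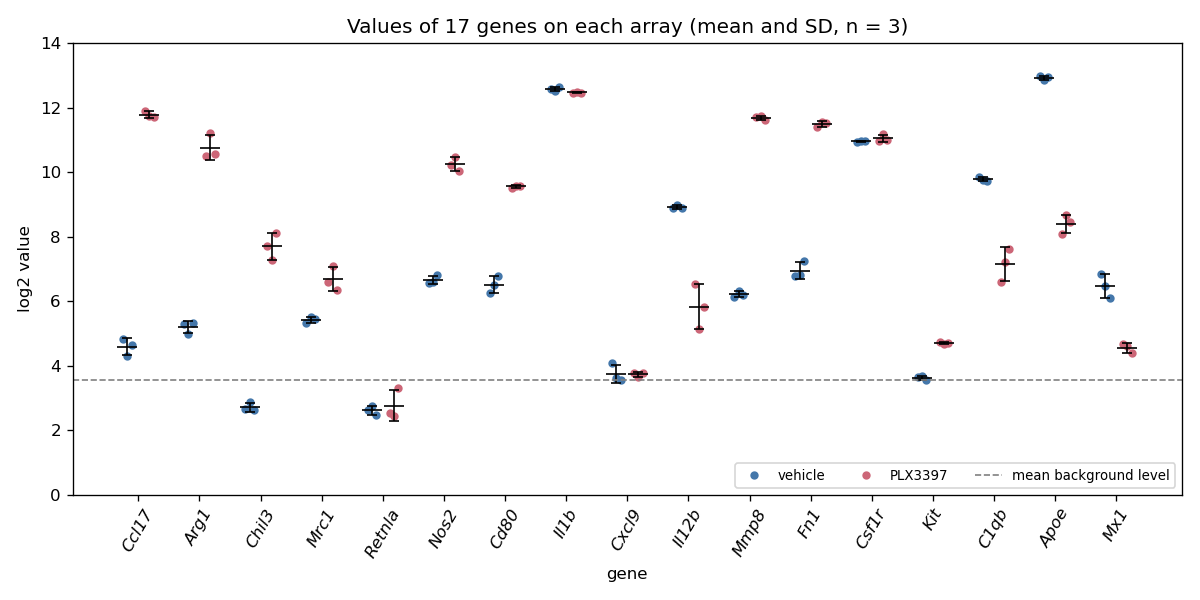
Log2 values (vertical axis) of selected genes (horizontal axis) on the 3 vehicle and 3 PLX3397 arrays, with points for arrays, bars for mean and SD, and a dashed line at the mean background level. Ccl17 lies near 4.59 in vehicle and 11.78 with PLX3397, Csf1r lies near 10.96 and 11.05, and Apoe falls from 12.92 to 8.40.

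Genes induced by IL4 in macrophages rose as a list. Of 25 measured members 19 rose and 3 fell (22 changed when adjusted over the list alone), with a median change of 1.26 (camera adjusted p = 8.36e-09; adjusted p = 0.036 with an estimated correlation). Besides Ccl17, Arg1 and Ccl22, the mannose receptor gene Mrc1 rose by 1.26 (SE 0.16), and the checkpoint ligand gene Pdcd1lg2 rose from a mean at the background level (3.51 ± 0.26) to 8.70 ± 0.13. The chitinase-like gene Chil3 was at least 17.9-fold higher. Retnla, another gene of this list, was below background in both groups, at 2.61 ± 0.13 and 2.76 ± 0.48.

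Genes induced by LPS and interferon-gamma went both ways. Of 25 members 8 rose and 9 fell (17 adjusted over the list alone), the median change was -0.02, the mean was 0.18, and the list test, in the direction of the median, gave an adjusted p of 0.575. Nos2, which makes nitric oxide, rose by 3.58 (SE 0.12, adjusted p = 1.56e-08), and the co-stimulatory gene Cd80 and the chemokine receptor Ccr7 rose by 3.04 and 3.35. The rise of Cd80 was as low as 2.32 over the alternatives. Il12b, a subunit of interleukins 12 and 23, fell by 3.10 (SE 0.26, adjusted p = 8.36e-06). Il1b was high in both groups (12.58 ± 0.06 and 12.47 ± 0.02, adjusted p = 0.287) and passed the threshold as lower when arrays were centred on their medians, and Cxcl9 was near background in both (3.74 ± 0.28 and 3.72 ± 0.07, adjusted p = 0.915).

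The list of matrix remodelling and angiogenesis genes had the largest median change of the 31 lists in the main comparison, 2.14. Over the alternatives its median ran from 1.98 to 2.18 and that of the IL4 list from 1.06 to 2.27, so the order can turn. Of the 23 measured matrix remodelling and angiogenesis genes 20 rose and 2 fell (22 adjusted over the list alone; camera adjusted p = 1.70e-12; adjusted p = 0.036 with an estimated correlation). Mmp8 rose by 5.48, the extracellular matrix gene Fn1 by 4.55, the metalloproteinase gene Mmp19 by 4.23 and the urokinase gene Plau by 3.67. Hypoxia and glycolysis genes rose in 16 of 22 cases and fell in 1 (17 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 2.70e-05; adjusted p = 0.454 with an estimated correlation). Among them Egln3, an oxygen sensor, rose by 3.83, the phosphofructokinase gene Pfkp by 1.81, Ankrd37 by 1.70 and Ero1a by 1.54.

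Chemokines and their receptors rose in 16 of 24 cases and fell in 2 (18 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 2.78e-05; adjusted p = 0.093 with an estimated correlation). Ccl12 rose by 3.78 and Ccl6 by 3.58, beside Ccl17 and Ccl22. Checkpoint and suppressive genes rose in 12 of 20 cases and fell in 2 (14 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.39e-04; adjusted p = 0.293 with an estimated correlation). The rises were led by Arg1 (5.57) and Pdcd1lg2 (5.20), which are also in the IL4 list. The ectonucleotidase gene Nt5e rose by 4.26 and the receptor gene Havcr2 by 3.85. NF-kB response genes went both ways, with 8 of 24 higher and 9 lower (17 adjusted over the list alone; camera adjusted p = 0.272): Ccl2 and Ccl4 rose by 1.71 and 1.38, while Nfkbiz and Tnf fell by 1.46 and 1.21.

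Interferon-stimulated genes were the 1 list called downward. Of 24 members 17 fell and 2 rose (20 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.65e-04; adjusted p = 0.514 with an estimated correlation). The antiviral genes Mx1 and Ifit1 fell by 1.91 and 1.85, and Ifi27l2a rose by 1.90. MHC class II genes rose in 6 of 11 cases and fell in 0 (6 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.010; adjusted p = 0.305 with an estimated correlation), led by the lysosomal reductase gene Ifi30 (1.54), H2-Oa (1.16) and H2-Ab1 (1.00). Of 14 MHC class I processing genes 5 rose and 5 fell (10 adjusted over the list alone; camera adjusted p = 0.575), with Erap1 lower by 1.10 and Psme2 by 0.85. Nlrc5 was 0.64 higher with its brightest probe set, but 0.13 lower on the mean of its probe sets.

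Phagocytosis, complement and Fc receptor genes fell in 15 of 25 cases and rose in 6 (22 adjusted over the list alone), a list that did not pass its test (median -0.43, camera adjusted p = 0.057) but passed narrowly without any 1 of the PLX3397 arrays (adjusted p = 0.050, 0.043 and 0.046 without replicates 1, 2 and 3) and with quantile normalisation, the replicate block or array weights, over a camera range of 0.043 to 0.454. The 3 chains of complement C1q fell, with C1qb lower by 2.64 and C1qc by 2.34, while Mfge8, which bridges phagocytes to dying cells, rose by 4.03. In the lipid handling and lysosome list 11 of 24 rose and 4 fell (16 adjusted over the list alone; camera adjusted p = 0.108, and 0.048 with centred arrays, over a camera range of 0.048 to 0.454), with the falls led by Apoe and by Nr1h3, a sterol-sensing receptor (-2.28), and the rises by Lgals3 (1.47) and the cholesterol exporter Abcg1 (1.03).

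**Figure D2:**
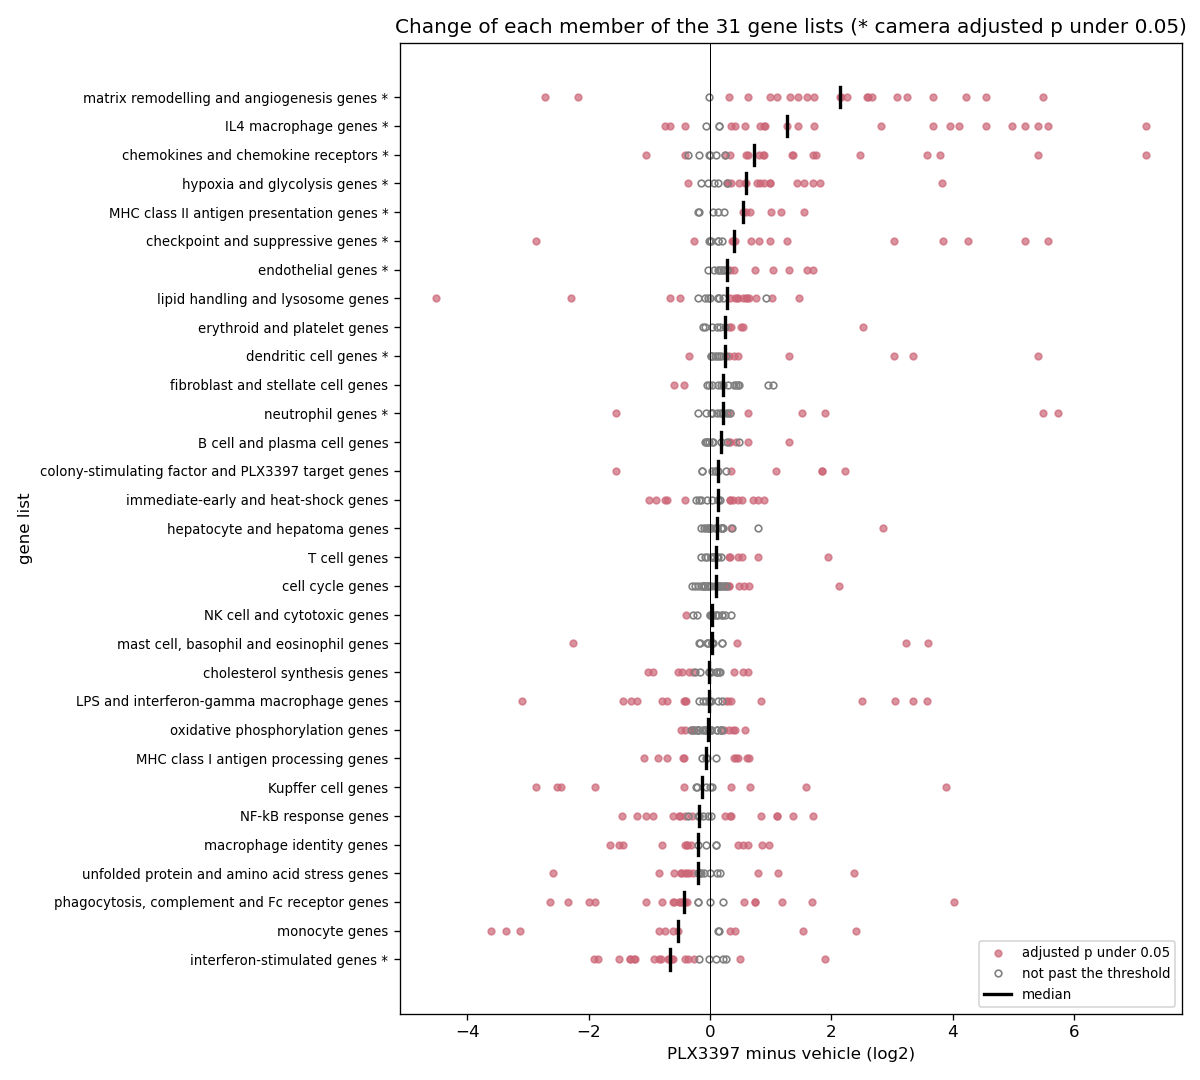
Change in log2 value, PLX3397 minus vehicle (horizontal axis), of each measured member of the gene lists (vertical axis), with filled points past the adjusted p threshold, open points not past it and bars at list medians. Medians run from -0.65 for interferon-stimulated genes to 2.14 for matrix remodelling and angiogenesis genes.

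Csf1r, which encodes the main target of the drug, was at 10.96 ± 0.02 in vehicle and 11.05 ± 0.11 with PLX3397 (change 0.09, SE 0.08, adjusted p = 0.441). Kit rose from near background in vehicle (3.62 ± 0.05) to 4.70 ± 0.03 (adjusted p = 2.33e-06). Flt3, near background, was 3.57 ± 0.03 and 3.83 ± 0.14 (adjusted p = 0.050). That value on the threshold ranged from 0.022 to 0.358 over the alternatives and was 0.029 without PLX3397 replicate 3. Of 13 colony-stimulating factor and PLX3397 target genes 5 rose and 1 fell (7 adjusted over the list alone; camera adjusted p = 0.062), and the list passed without vehicle replicate 3 (adjusted p = 0.043), with a variance trend (0.045) and with centred arrays (0.033, with a median of 0.0022), over a camera range of 0.033 to 0.396. The growth factor Csf1 rose by 2.23 and the receptor subunits Csf2rb and Csf2rb2 by 1.84 and 1.85, and Csf3r fell by 1.55. Macrophage identity genes went both ways, with 5 of 17 higher and 8 lower (14 adjusted over the list alone; camera adjusted p = 0.307), as Itgam rose by 0.97 and Maf and Siglec1 fell by 1.65 and 1.44.

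Kupffer cell genes, those of the resident macrophages of the liver, rose in 4 of 14 cases and fell in 5 (10 adjusted over the list alone; camera adjusted p = 0.272), with Id3, Folr2 and Spic lower by 2.87, 2.51 and 2.45 and Clec4n higher by 3.89. Of 13 monocyte genes 4 rose and 7 fell (11 adjusted over the list alone; camera adjusted p = 0.108), with Itga4, Ms4a4c and Treml4 among the falls and Ifitm6 higher by 2.40. Of 17 dendritic cell genes 8 rose and 1 fell (10 adjusted over the list alone; camera adjusted p = 0.009; adjusted p = 0.234 with an estimated correlation), led by Ccl22, Ccr7 and the integrin gene Itgax (3.04), which macrophages also express. Of 19 neutrophil genes 7 rose and 1 fell (8 adjusted over the list alone; camera adjusted p = 0.029; adjusted p = 0.396 with an estimated correlation), and the call ended with quantile normalisation (adjusted p = 0.057), on ranks and with either filter on mean level (camera adjusted p from 0.0093 to 0.396 over the alternatives). Its rises were led by Trem1, Mmp8 and Il1r2, which rose from near background (3.59 ± 0.26) to 5.48 ± 0.53, and its fall was that of Csf3r.

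Of 15 endothelial genes 7 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.001; adjusted p = 0.396 with an estimated correlation), with Kdr, Pecam1 and Vwf higher by 1.70, 1.60 and 1.30. Of 18 T cell genes 6 rose and 0 fell (6 adjusted over the list alone), led by the adaptor gene Lat (1.95) and Icos (0.79). Of 15 B cell and plasma cell genes 5 rose and 0 fell (5 adjusted over the list alone), led by Cd22 (1.29) and Cd79b (0.62). Of 16 NK cell and cytotoxic genes 14 were below background on all arrays, 0 rose, and Klrk1 fell by 0.40 below background (1 adjusted over the list alone). Of 21 hepatocyte and hepatoma genes 2 rose and 0 fell (1 adjusted over the list alone), the larger rise being that of the transferrin gene Trf (2.85). The smaller, of Vtn (0.35), lost the call in several alternatives, such as quantile normalisation (limma adjusted p = 0.078), and 1 gene rose without PLX3397 replicate 3. Of 15 fibroblast and stellate cell genes 0 rose and 2 fell (1 adjusted over the list alone), with Col1a1 lower by 0.60. Without PLX3397 replicate 3, 1 rose and 3 fell. The other fall, Col1a2 (-0.43), lost the call in several alternatives, such as quantile normalisation (limma adjusted p = 0.060). Dcn (0.95, limma adjusted p = 0.061) passed as higher in several, such as the replicate block (1.71e-04). Of 15 mast cell, basophil and eosinophil genes 3 rose and 1 fell (4 adjusted over the list alone), with Hdc and Gata2 higher by 3.59 and 3.22 and Ccr3 falling from 5.82 ± 0.48 to background (3.57 ± 0.06). Of 11 erythroid and platelet genes 5 rose and 0 fell (5 adjusted over the list alone), led by the chemokine gene Ppbp (2.52). The lists in this paragraph other than the endothelial list did not pass the list test, with adjusted p from 0.073 to 0.857. Over all genes 37.8% passed the threshold, and the median change shifted with level. Rises without falls in the lists that did not pass were therefore not shown to set them apart from other genes, and a difference is not excluded.

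The remaining lists did not pass the list test. Of 20 unfolded protein and amino acid stress genes 3 rose and 9 fell (12 adjusted over the list alone; camera adjusted p = 0.073), with Asns lower by 2.59 and Ddit4 higher by 2.37. Of 31 cell cycle genes 8 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 0.272), led by Top2a (2.12, but 0.88 on the mean of its probe sets) and Rrm2 (0.64). Of 18 cholesterol synthesis genes 3 rose and 6 fell (9 adjusted over the list alone; camera adjusted p = 0.434), with Sc5d and Idi1 lower by 1.02 and 0.94. Of 31 oxidative phosphorylation genes 5 rose and 5 fell (9 adjusted over the list alone; camera adjusted p = 0.538), with Sdhd higher by 0.58 and Cycs lower by 0.48. Of 21 immediate-early and heat-shock genes 8 rose and 5 fell (13 adjusted over the list alone; camera adjusted p = 0.884), with Klf6 lower by 1.01 and Ier3 higher by 0.89.

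Arrays of a group resembled each other more than arrays of different groups. Across genes, which are not independent replicates, Pearson correlations were 0.9961 to 0.9966 within vehicle, 0.9916 to 0.9963 within PLX3397 and 0.9512 to 0.9612 between groups, and the first principal component held 85.0% of the variance. PLX3397 replicate 3 stood apart on the second component (7.01% of the variance), with 37 genes over 2 log2 above the mean of the other arrays of its group, against 0 on each other array. Genes over 2 log2 below that mean numbered 7 on PLX3397 replicate 1, 11 on replicate 2 and 0 on the other arrays, and for replicates 1 and 2 the mean includes replicate 3. Without it, 7101 genes passed the threshold, 6658 of them shared with the full comparison. The IL4 list then had 19 rises and 2 falls, the matrix remodelling list 20 and 2, the hypoxia list 16 and 1, the chemokine list 15 and 2, the checkpoint list 11 and 1, and the interferon list 2 and 14.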

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

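The tests of the PLX3397 arrays as cultured cells, of exchanged labels and of replicate 3 were chosen after the results were seen, and the others in this part were planned, although the reading of the lymphocyte test was changed after its values were seen. Probe sets outside the gene-level comparison also differed between groups. Among 1621 probe sets with several gene symbols, 179 were higher and 393 lower with PLX3397, and among 5531 probe sets unnamed here, 805 were higher and 524 lower.

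Genes of macrophage polarisation differed between groups, and the description fields give each group a second name, of cultured cells. Nos2 had to be lower with PLX3397 by over 3 log2 if vehicle arrays held cells given LPS and interferon-gamma and treated arrays cells given IL4, and it was 3.58 higher, which argues against that reading of both groups, although Il12b fell by 3.10 as it needed. For the PLX3397 arrays alone the names stay open. The IL4 list had a median change of 1.26 and Arg1 and Chil3 rose by over 3 log2. Retnla, which had to rise by as much, stayed below background. Of the LPS and interferon-gamma list 8 genes rose, with Nos2, Ccr7 and Cd80 higher by over 3 log2 (Cd80 by as little as 2.32 over the alternatives), and 9 fell. An exchange of the 2 group labels cannot be told apart from the labels as given, because the drug does not fix the direction of its target's transcript, and Csf1r changed by 0.091. Of the 10 splits of the 6 samples into 3 and 3, 1, the real split, gave as many genes (7539, with 0 in the highest other split), but 10 splits are too few for a share under 0.05.

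Other cell types among the sorted cells are candidate sources of part of the difference. Endothelial and dendritic cells, whose lists passed upward (camera adjusted p = 0.001 and 0.009), though neither with an estimated correlation, were not tested as sources. The cells were sorted as macrophages, with the gate not given in the sources used here. The median change over Alb, Apoa1, Apoa2, Ttr, Fgb and Ahsg was 0.089, and Alb was below background on all arrays. This argues against RNA of hepatocytes or hepatoma cells that express these 6 genes. Tumour cells without these transcripts would not be seen this way. Krt8, of the same list, was above background on all arrays. It changed by 0.36 (limma adjusted p = 0.175), and by 0.63 without PLX3397 replicate 1 (limma adjusted p = 0.0014). The NK cell list, which had to move with the T and B cell lists, had a median change of 0.034, and the T cell list 0.098. Both met the criterion set beforehand for excluding lymphocytes, a median within 0.1 of 0 in at least 1 list. Lymphocytes are left open all the same, because 14 of the 16 NK cell genes were below background in both groups and the T cell median has a standard error of 0.14, wider than its distance from that bound. Neutrophils stay open: S100a8 rose by 1.52, so the bound set beforehand for excluding them was not met, but S100a9 changed by 0.33 (adjusted p = 0.115) and Cxcr2, Ngp and Retnlg, picked after their values were seen, were below background in both groups. An effect of PLX3397 on the macrophages, or on which macrophages were present at sorting, is the biological explanation the design gives and was not tested apart from these.

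PLX3397 replicate 3 had high levels of genes typical of fat, airway and squamous epithelium, led by Car3, Scgb1a1, Bpifa1, Ucp1, Krt4, Defb4 and Fabp4, which were 4.47 to 6.44 log2 above the mean of replicates 1 and 2. Matrix genes were higher too, among them Ogn (4.18), Bgn (3.13) and Sparc (2.75). Ogn was high on replicate 3 alone. Bgn and Sparc on replicate 3 (6.89 and 7.34) lay near the vehicle arrays (6.79 to 7.57 and 7.39 to 7.97). For Bgn and Sparc, replicates 1 and 2 were the low ones. A noisier array is argued against by the spread of receptor genes, 0.97 times the larger spread of the other 2 arrays, and hepatocyte RNA by a median of -0.00554 over 6 hepatocyte genes. Fat, airway or squamous epithelium RNA in that preparation stays open: further genes of these tissues, listed after the leading genes had been seen, had medians of 0.79, 0.18 and 0.42, short of the 1 log2 in at least 2 lists that had been set. Without Retn and Cyp2f2, which are among the genes over 2 log2 higher on that array, the fat and airway medians were 0.49 and 0.10. Skeletal muscle genes had a median of 0.41 and exocrine pancreas genes of -0.06. A count made after those medians were known, and not used to decide, found 13 of 43 such genes over 1 log2 higher (30.2%), against 1 of 13 muscle genes, 0 of 7 pancreas genes and 0.52% of all genes outside the 43. The 43 include Retn and Cyp2f2, without which 5 of 12 fat, 3 of 13 airway and 3 of 16 squamous genes were that high. No biological explanation was tested, since the design gives no group within PLX3397.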

How the results depend on the processing

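The filter on the background level was chosen after seeing the data, and all other alternatives were planned. The count of 7539 genes lay between 6332 and 7101 when 1 array was left out (higher 3124 to 3776, lower 3208 to 3601; lists 10 to 11), and was 7040 with quantile normalisation, 7423 for genes above background and 10031 over all probe sets. Centring each array on its median gave 2282 higher genes in place of 3900 among 7451 calls, as its own shift of the scale implies. Adding a change of at least 1 log2 left 1445 genes (640 higher, 805 lower), and with an unadjusted p 1447 (642 higher, 805 lower). The 10 list calls became 2 with an estimated correlation and 21 with fry, which does not compare a list with other genes. With the replicate number as a block, 7154 genes and 11 lists were called. Deviations of same-numbered samples correlated at -0.010, 0.008 and -0.013, so no pairing was seen over all genes together. Single genes can still follow the replicate number, as Dcn had a limma adjusted p of 0.061 without the block and 1.71e-04 with it. Over the alternatives other than fry, the camera adjusted p of the 8 lists lost with an estimated correlation was as low as 2.42e-07 (hypoxia), 1.76e-07 (chemokines), 6.01e-06 (checkpoint), 1.18e-05 (interferon), 5.20e-04 (endothelial), 0.00247 (dendritic cell), 0.00357 (MHC class II) and 0.0093 (neutrophil). Nlrc5 was reversed, at -0.13 on the mean of its probe sets, and the cause was not tested. Over the genes of the naming rule, 2143 comparisons with an alternative kept their side of the threshold, 24 gained and 24 lost the call. Genes called in both settings kept their direction among the 2143. Genes called in neither could change sign, as Csf1r did (-0.13 to 0.13). Most genes of the rule were picked for the size of their change in these data, so the counts do not carry over to other genes. A pseudocount of 16 was not run because the values are logarithms. Genes near the background level of 3.52 to 3.58 have compressed changes, so folds of dim genes are bounds.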

Other observations

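All tests in this part were chosen after the data were seen. Grouped by the start of their symbols, 338 gene families with at least 6 members above background were tested with camera, of which 62 passed (16 upward, 46 downward) and 0 passed with an estimated correlation. With quantile normalisation some of the 62 lost the call, such as Mrpl (camera adjusted p = 0.197), Polr (0.187), Tnfrsf (0.083) and Csf (0.062). The families below kept it and are examples from both directions, picked after their values were seen. Of 34 Rpl genes, which encode proteins of the large ribosomal subunit, 23 fell and 2 rose (median -0.42, camera adjusted p = 1.14e-06), and of 49 Eif genes of translation initiation 26 fell and 4 rose (median -0.30, camera adjusted p = 5.47e-05). Of 32 Ddx helicase genes 19 fell and 1 rose (median -0.47), of 10 Utp genes of ribosome assembly 8 fell (median -0.86), and the 7 measured Cct chaperonin genes all fell (median -0.92). With quantile normalisation the medians of these families were -0.61, -0.34, -0.40, -0.83 and -0.98. The ribosomal protein genes have many pseudogenes that can share probes. Of the 16 families that passed upward, the metalloproteinases had 12 of 16 Mmp genes higher and 1 lower (median 0.80), and the chemokines 10 of 14 Ccl genes higher and 1 lower (median 1.12).

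Among probe sets that name several genes, 1 of Ly6c1 and Ly6c2, monocyte surface markers that it does not separate, rose from 3.83 to 6.74 (adjusted p = 1.35e-06). In the monocyte list of single-gene probe sets, 4 of 13 genes rose and 7 fell. Among those shared by Ass1, which makes the precursor of arginine, and a predicted gene, the most changed rose from 8.22 to 11.58. Among those shared by the glutathione transferase genes Gsta1 and Gsta2 and predicted genes, the most changed rose from 3.69 to 7.54.

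The 3 Y-linked genes above background fell with PLX3397, Kdm5d by 1.16, Uty by 1.30 and Eif2s3y by 1.35. Cells of female mice are argued against by Xist, which was at 2.52 on the PLX3397 arrays, below background. Loss of the Y chromosome in part of the cells stays open. The falls lay within 0.19 log2 of each other, but this range cannot decide it, because it was judged after the falls had been seen. Falls of at least 1 log2 occurred in 805 genes, among them the X-linked Kdm6a (-1.24) and Usp9x (-1.04). A fall shared with X-linked partners is open for Uty and Eif2s3y, whose partners Kdm6a and Eif2s3x changed by -1.24 and -0.76, and the median over the partners of all listed Y-linked genes was -0.81. It is argued against for Kdm5d, whose partner Kdm5c changed by 0.036.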
